A study of Mus musculus with 144 samples.

How the data were processed

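Single cells sorted from the retinas of Iba1-EGFP mice were profiled by RNA sequencing, 1 library per cell. In this strain a fluorescent reporter is driven by Iba1, a gene of microglia and other macrophages, so that the cells can be collected by fluorescence-activated sorting. Per the labels, the mice were 16 weeks old and the cells came from untreated eyes or from eyes 2 or 4 days after crush of the optic nerve, an injury of the axons of retinal ganglion cells. Each of the 144 cells was assigned to its time point, plate and well by its labels. The 3 plates each held 18 untreated cells, 18 cells of day 2 and 12 cells of day 4. On every plate the time points sat in separate rows, so position on the plate and time point cannot be separated.

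Per the labels' protocols, cDNA was made and amplified from the lysed cell in 1 tube and turned into libraries by tagmentation with the Nextera XT kit. The labels mention no molecular identifiers, and strand was not used in any step taken here. Per the submitters' processing notes, Trim Galore 0.4.4, Trimmomatic 0.36, cutadapt 1.16, STAR 2.7.2b and featureCounts 1.6.1 were used with the builds GRCm38.p6 and mm10; the settings are not given in the sources used here. The authors deposited FPKM values, fragments per kilobase of exon and 1e+06 reads, in 1 table of 55364 genes by 144 cells with gene identifiers, symbols, exon positions and gene length. The deposited FPKM multiplied by gene length summed to 1e+09 in every cell, so each value is a share of the reads assigned to genes in that cell. No gene of the mitochondrial chromosome is among the rows (0 genes), and mitochondrial transcripts were therefore not analysed here.

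Depth was recovered from the step between low values: the most frequent value of FPKM times length in a cell is the value of 1 read. On simulated cells with known totals, this gave the true total in 12 of 12. The simulated cells held whole reads only, so recovery in cells with fractions of a read was not tested. Within a tolerance of 0.01 read, a median of 59.4% of the values above 0 in a cell were whole reads (range 49.1% to 69.1%). The other values were fractions of a read. Because whole reads were not recovered for nearly all genes, no count model was fitted. With M for 1e+06, cells had a median of 5.31 M assigned reads, from 0.190 to 18.9 M, and 3 cells had under 1 M. The closest pair of cells differed by up to 3932 FPKM in a gene, so no 2 cells held the same values.

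Cells with at least 500 genes at an FPKM of at least 1 were kept, which kept all 144. A gene was called measured when its FPKM was at least 1 in at least 10% of cells, which left 8695 genes. Expression was compared as the mean over cells of log2(FPKM + 1), with a pseudocount of 1. Differences on this scale understate the change of low genes. Of the 110 further rows that repeat a symbol, the row with the highest mean was used. The labels name no animal, so each time point counts as 1 sample of cells and no test across cells was made. No p-value, standard error or number of changed genes was computed. SDs describe the spread between cells. Every difference was recomputed within each of the 3 plates, a technical batch. Shares of cells have exact Clopper-Pearson 95% intervals, which cover counting error only.

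Gene lists were fixed before the data were examined. They covered homeostatic microglia, disease-associated microglia, cytokines and chemokines with NF-kB feedback genes, the interferon response, proliferation, antigen presentation, complement and phagocytosis, glycolysis, sterol synthesis and efflux, immediate-early and dissociation stress genes, ribosomal proteins, and markers of microglia and of other cell types of the retina and blood. For each list the median difference of its measured members was set beside its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries only. Lists with fewer than 3 measured members were given by the levels of their genes, a restriction made after seeing the data. Some further genes, among them 1 list fixed beforehand, are not reported here.

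The genes to be named were also set by a rule fixed before the data were examined. Gpr84, Tnf and Il1a, which the series title names, were always included. For each comparison with untreated cells the rule takes the 10 largest positive and the 10 largest negative differences, and for day 4 against day 2 the 5 largest of each. Eligible genes were at an FPKM of at least 1 in at least 30% of the cells of 1 group and had the same sign in all 3 plates. Mitochondrial, Rpl and Rps genes, names of Gm with digits, names ending in Rik or -ps, and names starting with LOC, AC or AL and digits were left out. Up to 4 measured members with the largest difference were added per list. Exon overlap between named genes and other rows was taken from the deposited exon positions.

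The procedure was tested on simulated data, in which cells were drawn from the untreated cells and 200 genes were multiplied by known factors. For the comparison of day 4 with untreated cells, the 50 genes multiplied by 4 had a median difference of 1.22 and 92% had the right sign, against a median of -0.03 in 6899 unchanged genes. The 50 genes multiplied by 2 had a median difference of 0.63. By chance 23.5% of the unchanged genes had the same sign in all 3 plates. The right sign in all 3 plates was found for 42% of the genes multiplied by 2 and 70% of those multiplied by 4. For day 2 against untreated cells these shares were 34% and 68%. A list of genes multiplied by 4 lay at percentile 100 in each of the 3 comparisons. A list of unchanged genes lay at percentile 41.4 for day 4 against untreated cells, 12.4 for day 2 against untreated cells and 85.5 for day 4 against day 2. The genes of this list were drawn at random, as were those of the random lists. Members of a real list may vary together between cells. Percentiles near 0 or 100 can then arise more readily, which the simulation did not test.

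Alternatives set before the data were examined were a pseudocount of 5, no filter on low values, all cells, only cells with at least 2000 genes, only cells with at least 5 of 10 microglia markers, rescaling of each cell to the same sum, the number of detected genes as a covariate, the log2 of the mean FPKM, the plate as a replicate block, and leaving out each plate. For shares of cells they were an FPKM above 0 or of at least 5. Chosen after seeing the data were a threshold of 20 FPKM for shares, with each plate left out, leaving out the cells under 1 M reads, removing the reads expected from other wells, cells with both genes expected within each plate of a time point, and differences relative to the median of all genes. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.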

Results

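The data comprised 144 single Iba1-EGFP cells of the mouse retina: 54 from untreated eyes, 54 from day 2 and 36 from day 4 after optic nerve crush. The series title names the 3 genes Gpr84, Tnf and Il1a. The comparisons therefore ask how expression of these genes, and of the programmes of microglia around them, stood at each time point. Each time point is 1 sample of cells with no replicate check, so differences are given with their values in the 3 plates and are not tested.

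Microglia markers were detected in the cells. At least 3 of 10 reached 20 FPKM in 54 of 54 untreated cells, 54 of 54 cells of day 2 and 35 of 36 cells of day 4, and every cell had at least 6 at an FPKM of at least 1. Markers of other cells were counted at the same level. At least 3 of 10 rod photoreceptor markers reached 20 FPKM in 4 of 54 untreated cells, 0 of 54 cells of day 2 and 1 of 36 cells of day 4. At least 3 of 8 markers of border macrophages reached it in 5, 8 and 2 cells, and at least 3 of 8 monocyte markers in 0, 2 and 0 cells. For neutrophil markers the numbers were 0, 0 and 1, for cones 1, 0 and 0, for Müller glia 1, 0 and 2, and for retinal ganglion cells 1, 0 and 0. A count of 0 of 54 cells allows a share of up to 6.60%, by counting error only. No cell reached 3 markers of T and NK cells, B cells, astrocytes, bipolar cells, amacrine and horizontal cells, endothelial cells, pericytes or pigment epithelium. Mean FPKM in untreated cells, at day 2 and at day 4 was 61.5, 25.96 and 40.8 for F13a1, the highest of the monocyte markers, 82.7, 128 and 43.5 for Csf3r of the neutrophil markers, 11.1, 21.5 and 20.7 for Cd79b of the B cell markers and 155, 228 and 216 for Gngt2 of the cone markers. It was 289, 389 and 223 for Pf4, the highest of the border macrophage markers, and 170.5, 120.03 and 51.7 for Glul, the highest of the Müller glia markers. Of the values above 0 of Csf3r and Gngt2, 56.9% and 69.7% were not whole reads, and exons of Gngt2 overlap those of Abi3.

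Pooled over plates, depth was similar between time points, but the number of genes was not. The median of assigned reads was 4.93 M in untreated cells, 5.32 M at day 2 and 5.80 M at day 4. Within plates depth differed more. In plates 1, 2 and 3 the median was 4.03, 6.32 and 4.49 M in untreated cells, 3.68, 6.75 and 6.66 M at day 2 and 5.18, 8.71 and 4.72 M at day 4. The median number of genes at an FPKM of at least 1 was 2793, 3473 and 3965. With each cell thinned to 2 M reads, the median number of genes with at least 5 reads was 2744 in 50 untreated cells, 3466 in 45 cells of day 2 and 3659 in 36 cells of day 4, leaving out 4, 9 and 0 shallower cells. The 20 genes with most reads took a median of 25.1%, 22.8% and 17.6% of the reads. The median difference of all 8695 measured genes was accordingly above 0, at 0.21 for day 2 and 0.45 for day 4 against untreated cells, and differences are to be read against these shifts.

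Day 4 after crush was compared with no treatment. Pooled over plates, cells of day 4 had higher Tnf, Gpr84 and several chemokines, and higher glycolytic, interferon-response and proliferation genes. Homeostatic microglia genes were lower relative to other genes. Mean log2(FPKM + 1) of Tnf, the tumour necrosis factor gene, was 6.60 ± 3.81 (SD over 36 cells) at day 4 and 2.73 ± 2.42 (SD over 54 cells) in untreated cells, and its mean FPKM was 538 against 42.7, 12.6-fold higher. Gpr84, a receptor for medium-chain fatty acids on myeloid cells, was at 6.43 ± 3.42 against 3.69 ± 3.12, with a mean FPKM of 399 against 113, 3.53-fold higher. Il1a, the interleukin-1 alpha gene, was at 7.37 ± 3.18 against 5.04 ± 3.25, with a mean FPKM of 631 against 252, 2.50-fold higher. The difference was 3.80, 5.82 and 1.98 in plates 1, 2 and 3 for Tnf, and 2.47, 5.16 and 0.59 for Gpr84. For Il1a it was 2.63, 4.48 and -0.13, so that no difference of the pooled sign was seen in plate 3. The median difference of all measured genes in plate 3 was 0.32, so Gpr84 stood little above the general shift there. Taken as a list, the 3 genes had a median difference of 2.74, at percentile 99.6 of random lists. In plate 3 the median of this list was 0.59, at percentile 47.9.

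The 3 genes lie on GRCm38: Gpr84 (ENSMUSG00000063234) on chromosome 15 from 103308235 to 103310612, Tnf (ENSMUSG00000024401) on chromosome 17 from 35199381 to 35202007, and Il1a (ENSMUSG00000027399) on chromosome 2 from 129299610 to 129309972, all on the minus strand and counted over their exons. Exons of Gpr84 overlap those of Gm49482, and exons of Il1a those of Gm14023, so reads of these pairs cannot be told apart without strand. Of their values above 0, 60.4% for Gpr84 and 52.8% for Il1a were not whole reads. Genes for which this share was over 50% are uncertain in level, these 2 included, and the source of the fractions was not tested. With the number of detected genes as a covariate the difference of Gpr84 was 1.20, of Tnf 2.49 and of Il1a 0.60. Without plate 2 the difference of Gpr84 was 1.53 and that of Il1a was 1.25.

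Pooled over plates, a larger share of cells held high values of the 3 genes at day 4 than in untreated cells. In plate 3 the share was not larger for Il1a. For Gpr84 it was little larger there, with 7 of 12 cells of day 4 against 9 of 18 untreated cells. At a threshold of 20 FPKM, chosen after seeing the data, Gpr84 was high in 16 of 54 untreated cells (29.6%, 95% interval 17.98% to 43.6%), 21 of 54 cells of day 2 (38.9%, 25.9% to 53.1%) and 25 of 36 cells of day 4 (69.4%, 51.9% to 83.7%). Tnf was high in 10 (18.5%, 9.25% to 31.4%), 16 (29.6%, 17.98% to 43.6%) and 24 cells (66.7%, 49.03% to 81.4%). Il1a was high in 21 (38.9%, 25.9% to 53.1%), 30 (55.6%, 41.4% to 69.1%) and 26 cells (72.2%, 54.8% to 85.8%). Between 10 and 40 FPKM, near this threshold, lay 1, 8 and 1 cells for Gpr84, 4, 7 and 1 for Tnf, and 6, 6 and 3 for Il1a. The plates differed: at day 4, Gpr84 was high in 6, 12 and 7 of 12 cells in plates 1, 2 and 3, in cells of day 2 in 1, 11 and 9 of 18, and in untreated cells in 3, 4 and 9 of 18. Tnf was high in 7, 11 and 6 cells of day 4, 2, 8 and 6 of day 2 and 3, 1 and 6 untreated cells, and Il1a in 8, 12 and 6, in 8, 12 and 10 and in 5, 6 and 10. Without plate 3 the shares of untreated cells were 19.4% for Gpr84 and 11.1% for Tnf.

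At the threshold of 1 FPKM set beforehand, most cells counted as positive. Gpr84 was found in 44 untreated cells (81.5%, 95% interval 68.6% to 90.7%), 45 cells of day 2 (83.3%, 70.7% to 92.1%) and 35 cells of day 4 (97.2%, 85.5% to 99.9%). Tnf was found in 39 (72.2%, 58.4% to 83.5%), 41 (75.9%, 62.4% to 86.5%) and 33 cells (91.7%, 77.5% to 98.2%), and Il1a in 53 (98.1%, 90.1% to 99.95%), 54 (100%, 93.4% to 100%) and 36 cells (100%, 90.3% to 100%). Low values are close to the background between wells. Among 93 genes with over 95% of their reads in 1 cell, another well of the same column of the plate held a read in 70.0% of cases, and a well of another plate in 3.91%.

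**Figure D1:**
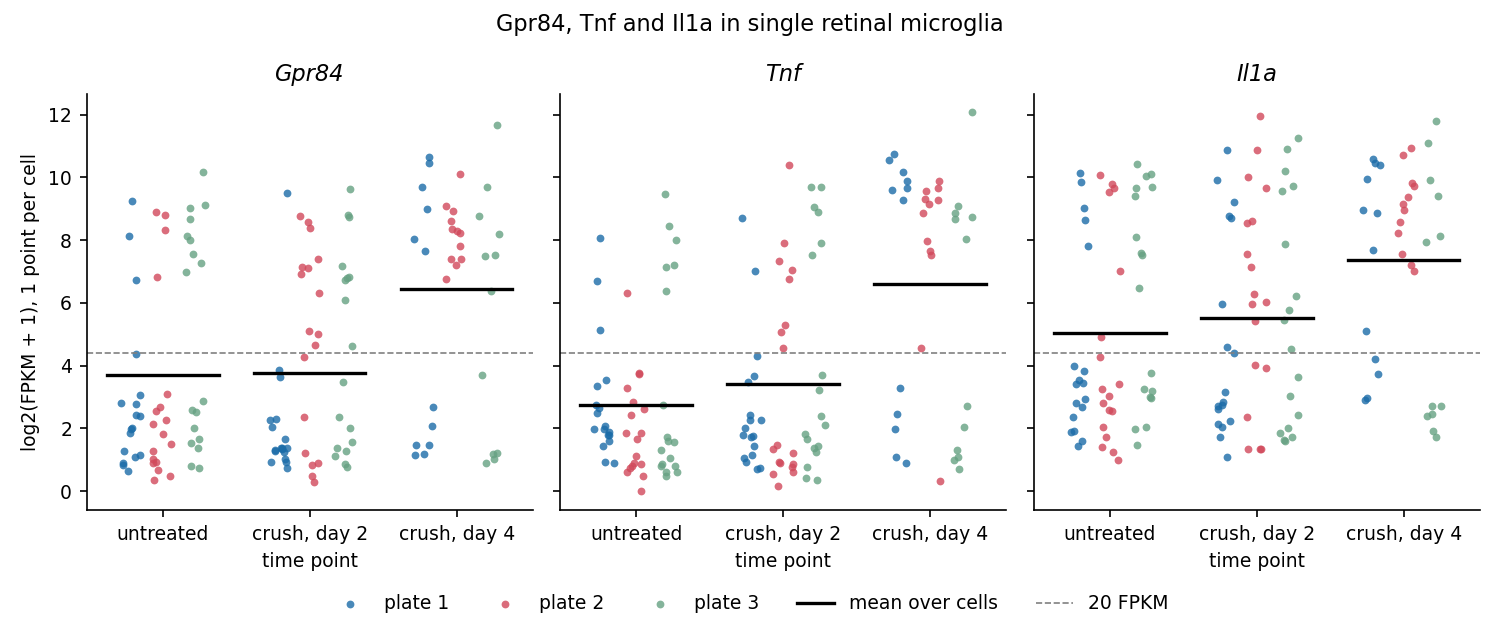
Each point is 1 cell, with log2(FPKM + 1) on the vertical axis and the time point on the horizontal axis; colours are plates, bars are means over all cells of a time point and the dashed line marks 20 FPKM. Gpr84 lies above the line in 16 of 54 untreated, 21 of 54 day 2 and 25 of 36 day 4 cells, including 12 of 12 day 4 cells of plate 2.

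Chemokine and cytokine genes were among the largest differences of day 4. The list of cytokines, chemokines and NF-kB feedback genes had a median difference of 1.42 over 17 measured members, at percentile 99.7 of random lists, with 1.77, 2.36 and 0.82 in plates 1, 2 and 3 and percentile 83.7 in plate 3. Of its members, 8 were higher and 1 lower in all 3 plates, where 43.4% and 3.94% of all genes were. The list median was 0.20 with the number of detected genes as a covariate, 0.90 without plate 2 and 0.78 on the scale of log2 of the mean FPKM. Ccl12, a monocyte chemoattractant, had a mean log2 value of 12.49 at day 4 and 8.16 in untreated cells, a difference of 4.33 (5.22, 4.97 and 2.81 by plate). Ccl4, another chemokine, was at 9.46 against 6.06, and Cxcl16, a transmembrane chemokine, at 5.27 against 2.28. Tlr2, a receptor for bacterial lipopeptides, was at 6.07 against 2.63.

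Glycolytic enzymes were higher together. The list had a median difference of 2.06 over 14 members, at percentile 100, with 2.33, 2.32 and 1.43 by plate, and 12 members were higher in all 3 plates. The difference was 2.89 for Ldha, lactate dehydrogenase A, 2.89 for Aldoa, 2.84 for Pkm and 2.64 for Eno1. Of the values of these 4 genes above 0, 77.8%, 59.7%, 87.5% and 95.8% were not whole reads, so their levels are uncertain. The interferon response list had a median difference of 1.71 over 15 members, at percentile 100, with 1.26, 2.32 and 1.20 by plate, and 13 members were higher in all plates. Bst2, which tethers virus particles, differed by 2.48, Irf7, a transcription factor of the interferon response, by 2.37, Ifitm3 by 2.37 and Oas1a by 2.11.

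The proliferation list had a median difference of 1.57 over 19 members, at percentile 100, with 0.73, 2.46 and 1.40 by plate. Of these, 14 members were higher in all plates and 0 lower. Tubb5, a tubulin, differed by 3.00, Stmn1, a regulator of microtubules, by 2.34, and Mcm3 and Mcm6, subunits of the replicative helicase, by 2.51 and 2.33. With the number of detected genes as a covariate, the list medians were 0.57 for proliferation, 0.90 for the interferon response and 1.20 for glycolysis. The ribosomal protein list had a median of 0.98 over 80 members, at percentile 94.8, with 0.99, 1.09 and 0.99 by plate, and 0.22 on the scale of log2 of the mean FPKM. Its 4 largest differences were those of Rpl29 (3.11), Rps27l (2.66), Rpl17 (2.46) and Rpl38 (2.43).

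Of the other genes with the largest positive differences, Nme1, a nucleoside diphosphate kinase, was at 5.83 against 1.54, and Mif, macrophage migration inhibitory factor, at 7.35 against 3.35. Psmb6 and Psma5, subunits of the 20S proteasome, differed by 3.57 and 3.49. Ran, the GTPase of nuclear transport, differed by 3.49 and its binding protein Ranbp1 by 3.56. For Nme1, Mif, Ran and Ranbp1, 64.1% to 76.2% of values above 0 were not whole reads, and their levels are uncertain. The same holds for Psma5, Cxcl16, Oas1a, Stmn1, Itgam, Hsp90aa1, Rpl29, Rpl17, Rpl38, Ltc4s, Dazap2 and Glul, with shares from 51.7% for Cxcl16 to 93.7% for Rpl29. Exons also overlap those of Gm20390 for Nme1, Gm49776 and Trmt2a for Ranbp1, 1700010K24Rik for Psma5, Gm23634 for Stmn1, Zmynd15 for Cxcl16, Phrf1 for Irf7 and Fam57b for Aldoa. The same is true of Gm49759 for Pkm, Gm49368 for Itgam, Gm26542 for Ltc4s, Teddm2 and Mir8114 for Glul, Hmgxb3 for Csf1r, Gm17233 and Rb1 for Rcbtb2, Gm42793 for Spp1, Il1bos for Il1b and Gm30489 for F13a1. For Tnf, Ccl12, Ccl4 and Tlr2 the share of values that were not whole reads was between 1.42% and 12.5%.

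Homeostatic microglia genes were lower relative to other genes. Their list had a median difference of -0.43 over 15 members, at percentile 0.01, with -0.01, 0.37 and -1.11 by plate and percentiles 1.81, 4.16 and 0.00. The members did not move alike: Csf1r, the receptor that microglia need to survive, differed by -0.90 and Slc2a5, a fructose transporter, by -1.03, while Olfml3 and Fcrls differed by 1.84 and 1.59. Without plate 3 the median of the homeostatic list was 0.03, without plate 1 -0.61 and without plate 2 -0.78. It was -1.19 with detected genes as a covariate and -0.57 on the scale of log2 of the mean FPKM. The microglia marker list, which shares members with the homeostatic list, had a median of -0.31, at percentile 0.05, with -0.08, -0.13 and -0.97 by plate. Disease-associated microglia genes had a median of 0.51 over 16 members, at percentile 24.2, with 0.91, 1.35 and 0.05 by plate. In that list Lpl, lipoprotein lipase, differed by 2.45, Cst7, a cystatin, by 2.22 and Clec7a by 1.73, while Apoe differed by -1.46 (-2.62, -2.51 and 0.76 by plate).

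The largest negative differences of day 4 were those of Ypel3, at 1.93 against 4.43 (-2.49, by plate -2.66, -2.28 and -2.55), and Selenop, a selenium carrier, at 6.65 against 8.83 (-2.18). Ccdc152, whose exons overlap those of Selenop, differed by -2.07, and the reads of the pair cannot be told apart. Hpgd, which degrades prostaglandins, differed by -1.97, Dhrs3, a retinal reductase, by -1.85, Ltc4s, leukotriene C4 synthase, by -1.82, and Tsc22d3, a gene induced by glucocorticoids, by -1.66. Rcbtb2 differed by -1.64, Dazap2 by -1.51 and Glul, glutamine synthetase, by -1.45. Glul is also a marker of Müller glia, whose list of 3 measured members had a median of -0.28, at percentile 1.63, with -0.79, -0.59 and -0.39 by plate. It was -0.027 without plate 1, -0.69 without plate 3 and 0.17 without the filter on low values. The list of border macrophage markers had a median of -0.60 over 5 members, at percentile 0.00, with -0.99, -1.02 and -0.01 by plate. It was -0.17 without plate 1, -1.24 without plate 3, -1.002 with detected genes as a covariate and -1.25 on the scale of log2 of the mean FPKM.

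At day 4 antigen presentation had a median of -0.08 over 12 members, at percentile 0.10 of random lists with a median of 0.76. It was -0.18, 0.28 and 0.61 by plate, at percentiles 0.89, 2.01 and 61.7, so plate 3 did not share the low rank. It was 0.23, 0.0997 and 0.024 with plates 1, 2 and 3 left out in turn. With detected genes as a covariate the list median was -0.42, and on the scale of log2 of the mean FPKM -0.062. In this list Cd86 differed by 1.19 and H2-Aa by -0.93. Complement and phagocytosis had a median of 0.36 over 18 members, at percentile 5.76, with 0.20, 0.60 and -0.06 by plate, and included Cd68, a lysosomal protein of phagocytes, at 1.69 and Itgam at 1.56. Sterol synthesis and efflux had a median of 0.46 over 12 members, at percentile 77.0, with 0.13, 0.69 and 0.15 by plate, led by Msmo1 at 1.05. The immediate-early and dissociation stress list had a median of 0.44 over 21 members, at percentile 13.4, with 0.81, 0.93 and -0.30 by plate. Over detected genes as a covariate, the log2 of the mean FPKM and each plate left out, medians ranged from 0.19 to 0.79 for disease-associated microglia, -1.01 to 0.023 for the microglia markers, -0.55 to 0.47 for complement and phagocytosis, -0.063 to 0.61 for sterol genes and -0.98 to 0.85 for immediate-early and stress genes. Among the stress genes Hsp90aa1 differed by 2.18, and Fos by 1.1597 but by -0.40 on the scale of log2 of the mean FPKM.

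**Figure D2:**
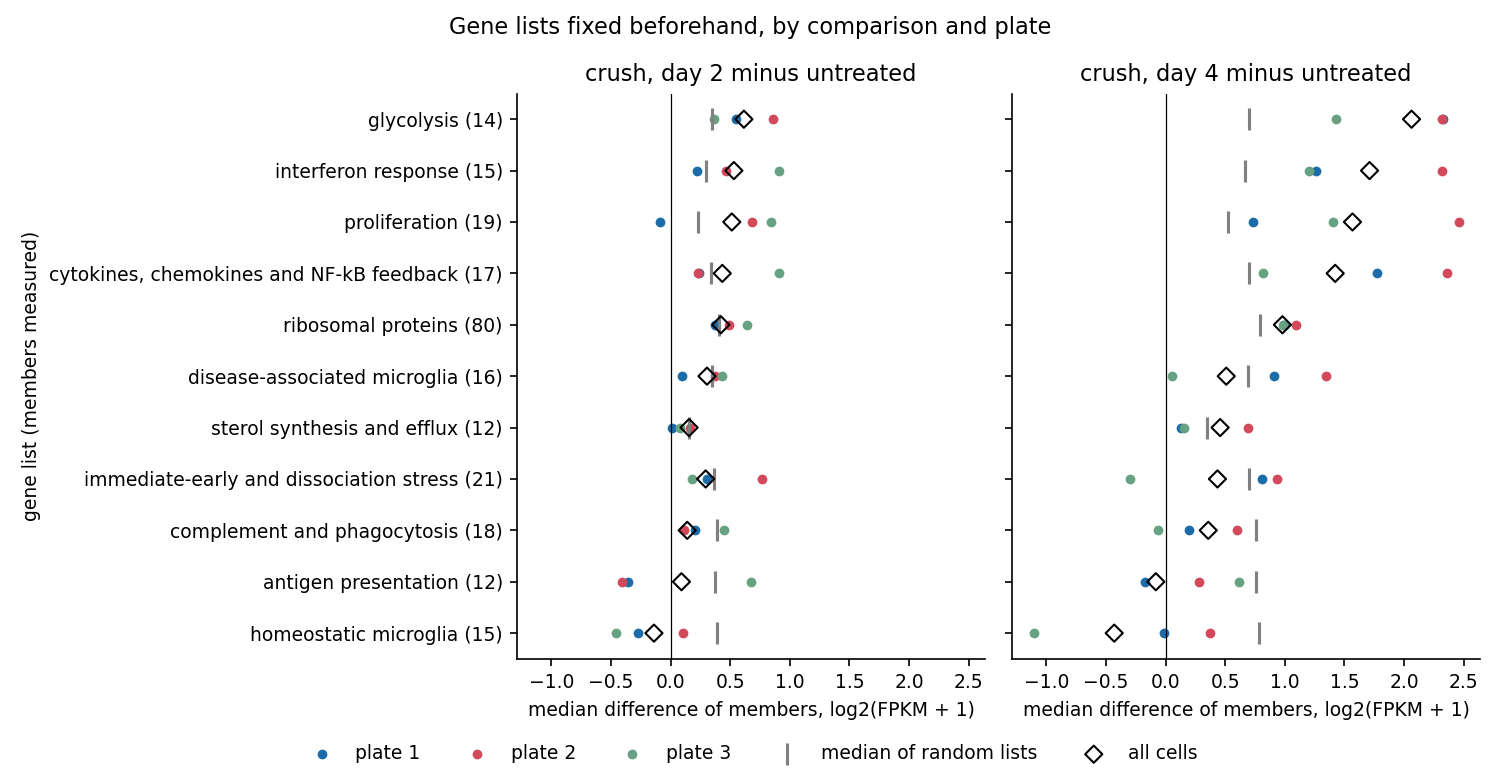
Median difference of the measured members of each list in log2(FPKM + 1), for day 2 (left) and day 4 (right) minus untreated cells; diamonds are all cells, points are plates and grey ticks are the medians of matched random lists. At day 4 glycolysis (2.06), interferon response (1.71), proliferation (1.57) and cytokines (1.42) lie right of their random lists, and homeostatic microglia (-0.43) left.

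Day 2 after crush was then compared with no treatment. The proliferation, glycolysis and interferon response lists lay at percentiles of 96.9 to 99.7 of random lists with all plates pooled and Trem2 was lower. Gpr84, Tnf and Il1a had no difference of one sign in all plates. This does not exclude a change, since only 34% of genes multiplied by 2 met that rule in the simulation. Gpr84 differed by 0.09 (-0.87, 1.73 and -0.60 by plate), Tnf by 0.67 (-0.20, 1.52 and 0.69) and Il1a by 0.47 (0.24, 1.78 and -0.62). Mean FPKM at day 2 was 91.5 for Gpr84, 108 for Tnf and 390 for Il1a, which is 0.810, 2.53 and 1.55 times that of untreated cells.

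Atp5mpl, a small subunit of the ATP synthase, had the largest positive difference among the named genes of day 2, with a mean log2 value of 4.61 at day 2 against 2.21, a difference of 2.41 (2.27, 2.53 and 2.42 by plate). Mdh1, cytosolic malate dehydrogenase, differed by 2.35 and Cox7b, a subunit of cytochrome c oxidase, by 1.95. Stmn1 differed by 2.21, Lpxn, an adaptor of focal adhesions, by 2.12, Itgb5, an integrin subunit, by 1.91 and Cotl1, which binds actin, by 1.86. Ppib and Snx22, with differences of 1.99 and 1.94, have overlapping exons and cannot be told apart. Mir3082, at 1.94, lies within exons of Jmjd8 and Stub1 and cannot be told apart from them.

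Trem2, a lipid receptor of microglia that belongs to the disease-associated list, had the largest negative difference, at 6.57 against 7.71 (-1.14, by plate -1.15, -1.33 and -0.94). Pacc1, a chloride channel, differed by -1.10, Cd48 by -1.07, Ccl5, a chemokine, by -1.06, Hhex, a transcription factor, by -1.03 and Fscn1, which bundles actin, by -0.97. Golm1, Dazap2, Dpm2 and Aprt differed by -0.96, -0.93, -0.93 and -0.89. Exons of Mdh1 overlap those of Wdpcp and exons of Golm1 those of Naa35. Stmn1, Ppib, Golm1 and Dazap2, and among list members Hmgb2, Ifi27l2a and H2-D1, had 52.1% to 96.5% of values that were not whole reads and are uncertain.

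Proliferation had a median of 0.51 at day 2 over 19 members (percentile 99.7), with -0.09, 0.68 and 0.84 by plate and percentiles of 16.4, 98.5 and 99.5. It included Tubb5 at 1.58, Cenpa, a centromere histone, at 1.36, and Hmgb2 at 1.17. Glycolysis had a median of 0.61 (percentile 97.1), with 0.55, 0.86 and 0.37 by plate, percentiles of 97.2, 95.9 and 39.8, and 10 of 14 members higher in all plates, where 28.3% of all genes were. In it Aldoa differed by 1.43, Eno1 by 1.27 and Gpi1 by 1.24. The interferon response had a median of 0.53 (percentile 96.9), with 0.22, 0.46 and 0.91 by plate and percentiles of 73.9, 66.2 and 98.4. In it Ifi27l2a differed by 1.24 and Irf7 by 1.04. With detected genes as a covariate, on the log2 of the mean FPKM and with each plate left out, medians ranged from 0.27 to 1.34 for proliferation, 0.29 to 0.75 for glycolysis and 0.30 to 1.06 for the interferon response.

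Homeostatic microglia genes had a median of -0.14 at day 2 (percentile 0.04, by plate -0.27, 0.11 and -0.46), with P2ry13 at -0.81 and Csf1r at -0.69, but Fcrls at 1.33 and Olfml3 at 1.03. Without plate 3 the list median was 0.03, without plate 1 -0.22, without plate 2 -0.45 and with detected genes as a covariate -0.49. The microglia markers had a median of -0.09 (percentile 0.37), the border macrophage markers 0.33 (percentile 61.4, by plate -0.76, -0.27 and 1.34) and the Müller glia markers -0.29 (percentile 1.44). Disease-associated microglia genes had a median of 0.31 (percentile 35.4, by plate 0.10, 0.37 and 0.43), with Lgals3, Cst7 and Spp1 at 1.08, 1.02 and 0.95. Cytokines and chemokines had a median of 0.43 (percentile 78.1, by plate 0.24, 0.23 and 0.91), with Ccl12 at 1.27 and Ccl4 at 1.18, and a median of -0.15 with the number of detected genes as a covariate. The median of antigen presentation was 0.09 (percentile 3.23), with H2-D1 at -0.85. By plate it was -0.35, -0.40 and 0.67, at percentiles 2.63, 0.01 and 77.6. Medians were 0.14 for complement and phagocytosis (percentile 2.26), with Fcgr1 at -0.77. They were 0.16 for sterol genes (percentile 50.1), 0.29 for immediate-early and dissociation stress genes (percentile 26.7), with Ier3 at 1.23 and Atf3 at 1.07, and 0.42 for ribosomal proteins (percentile 57.4). Over the same alternatives medians ranged from -0.44 to 0.14 for the microglia markers, -0.33 to 0.52 for the border macrophage markers, -0.53 to -0.015 for the Müller glia markers, 0.17 to 0.64 for disease-associated microglia, -0.38 to 0.19 for antigen presentation, -0.31 to 0.28 for complement and phagocytosis, -0.12 to 0.22 for sterol genes and -0.55 to 0.45 for immediate-early and stress genes.

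**Figure D3:**
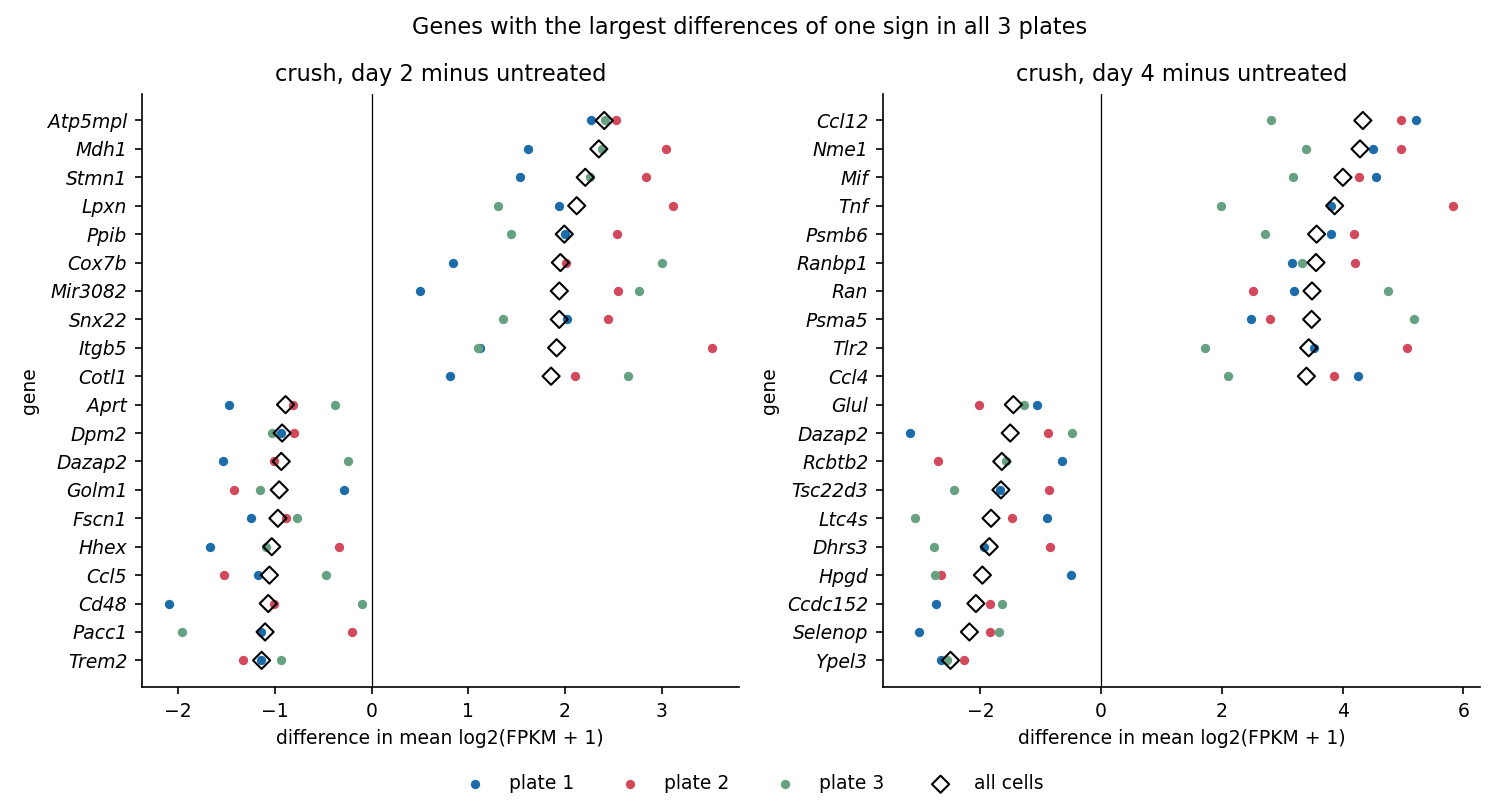
Differences in mean log2(FPKM + 1) of the genes with the 10 largest positive and 10 largest negative values of one sign in all 3 plates, for day 2 (left) and day 4 (right) minus untreated cells; diamonds are all cells and points are plates. The largest differences are 2.41 for Atp5mpl at day 2 and 4.33 for Ccl12 at day 4, and the most negative are -1.14 for Trem2 and -2.49 for Ypel3.

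Day 4 compared with day 2 showed where the later time point stood apart. Tnf was higher by 3.20 (4.00, 4.30 and 1.29 by plate), Gpr84 by 2.65 (3.34, 3.43 and 1.19) and Il1a by 1.86 (2.39, 2.69 and 0.50), each with the same sign in all plates. Nme1 differed by 3.96, Ranbp1 by 3.25, Nop56, a protein of ribosomal RNA processing, by 3.25 and Nutf2, which imports Ran into the nucleus, by 3.13, with 66.2% to 93.8% of their values not whole reads and uncertain levels. Exons of Nop56 also overlap small nucleolar RNAs and Idh3b.

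Lower at day 4 than at day 2 were Ypel3 (-2.51), Lst1 (-2.12), S100a1 (-1.96), Apoe, the apolipoprotein of lipid export (-1.89, by plate -2.73, -2.44 and -0.49), and Ramp1 (-1.85). Mean FPKM of Apoe was 7067 in untreated cells, 7705 at day 2 and 1999 at day 4. Border macrophage markers had a median of -0.82 (percentile 0.00, by plate -0.56, -0.79 and -1.11), and -1.51 on the scale of log2 of the mean FPKM.

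Medians for day 4 minus day 2 were 1.29 for glycolysis (percentile 99.99, by plate 1.70, 1.37 and 0.78), 1.15 for cytokines and chemokines (percentile 99.99, by plate 1.59, 1.96 and 0.03, and 50.2 as percentile in plate 3), 0.92 for the interferon response (percentile 99.6) and 0.89 for proliferation (percentile 100). The median of cytokines and chemokines was 0.44 with detected genes as a covariate, 0.64 without plate 2, 1.99 without plate 3 and 0.63 on the scale of log2 of the mean FPKM. Over these alternatives glycolysis had 0.75 to 1.66, the interferon response 0.61 to 1.18 and proliferation 0.52 to 1.19. In the last of these, Mcm3 differed by 2.32, Mcm2 by 1.92, Mcm5 by 1.84 and Mcm6 by 1.82. Medians were 0.29 for disease-associated microglia (percentile 45.04), -0.06 for homeostatic microglia (percentile 5.24) and for the microglia markers (percentile 9.48), and 0.13 for antigen presentation (percentile 14.8). They were 0.38 for complement and phagocytosis (percentile 52.4), 0.25 for sterol genes (percentile 66.6), 0.36 for immediate-early and dissociation stress genes (percentile 53.4), 0.39 for ribosomal proteins (percentile 63.9) and 0.01 for the Müller glia markers (percentile 24.3). Ranges over these alternatives that included 0 were -0.047 to 0.90 for disease-associated microglia, -0.35 to 0.088 for homeostatic microglia, -0.46 to 0.066 for the microglia markers, -0.21 to 0.20 for antigen presentation, -0.076 to 0.64 for complement and phagocytosis, -0.50 to 0.50 for immediate-early and stress genes, -0.16 to 0.46 for ribosomal proteins and -0.68 to 0.46 for the Müller glia markers.

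Within a time point, cells high in Gpr84 were more often also high in Tnf and Il1a than independent detection over the time point would give, with a smaller excess within plates and levels of detected genes. At 20 FPKM, Gpr84 and Tnf were both high in 6 untreated cells where 2.96 were expected, in 13 cells of day 2 where 6.22 were expected, and in 21 cells of day 4 where 16.7 were expected. Gpr84 and Il1a were both high in 12, 18 and 23 cells, where 6.22, 11.7 and 18.1 were expected. With the plates of a time point taken separately, chosen after seeing the data, 3.72, 8 and 18 were expected for Tnf and 7.17, 12.8 and 19.5 for Il1a. Over the 3 time points the excess was 14.1 cells for Tnf and 17.1 for Il1a, 10.3 and 13.6 within plates, and 5.39 and 6.61 within plates and upper or lower part of the genes detected. Il1b was high together with Gpr84 in 1, 1 and 4 cells, against 0.30, 1.56 and 2.78. C1qa, a complement gene of nearly all microglia, was high in all but 1 of the cells, so its numbers equal those expected but for 24 against 24.3 at day 4.

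At the threshold of 1 FPKM set beforehand, the numbers with both were close to those expected. They were 32, 34 and 32 for Tnf against 31.8, 34.2 and 32.1, and 44, 45 and 35 for Il1a against 43.2, 45 and 35. Il1a was found in 53 of 54 untreated cells and in all cells of day 2 and day 4, so its numbers were fixed or nearly fixed. Gpr84 was found in 35 of 36 cells of day 4, so the number for Tnf at day 4 was nearly fixed too. The numbers for Il1a, and that for Tnf at day 4, say nothing about a link between the genes. For Tnf in untreated cells and at day 2 the numbers were free to exceed those expected, and no excess was seen at this threshold. Low values that are close to the background between wells also count as positive here. For Il1b the numbers with both were 17, 12 and 10 against 14.7, 11.7 and 9.72.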

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

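In this part the thresholds of 20 FPKM, the cells under 1 M reads, the removal of cross-well reads and the differences relative to all genes were chosen after the results were seen. The differences of Tnf, Gpr84 and Il1a between day 4 and untreated cells kept their direction in every alternative run, with a range of 2.49 to 4.81 for Tnf, 1.20 to 3.82 for Gpr84 and 0.60 to 3.55 for Il1a. With the plate as a replicate block the values equal the pooled ones (2.74 for Gpr84), because every plate holds the same numbers of cells per time point, so this setting says nothing about stability. Using all cells, or only cells with at least 5 microglia markers, removed no cell. A value counted as unchanged when it lay within the SD of the 3 plate values from the main value. Its sign was checked only where the 3 plates agreed in sign. Of 198 differences of other named genes, 111 were unchanged by this rule on the scale of log2 of the mean FPKM, 146 with detected genes as a covariate, 170 with a pseudocount of 5 and 183 in cells with at least 2000 genes. The values that follow, which are list medians unless a gene is named, moved beyond that SD, or changed sign where the plates agreed. Some sign changes within that SD are therefore not listed, such as those of antigen presentation for day 4 minus untreated with plates left out. Of the other named genes only those that changed sign are listed, and of the marker lists only a part. Not listed is, for example, -1.01 for the microglia markers for day 4 minus untreated with detected genes as a covariate. The cause of these changes was not tested.

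With a pseudocount of 5, values for day 2 minus untreated were 0.032 for sterol genes. For day 4 minus untreated they were 1.46 for glycolysis and 0.81 for ribosomal proteins. The values for day 4 minus day 2 were 0.59 for proliferation and 0.30 for ribosomal proteins. Without the filter on low values, values for day 2 minus untreated were 0.053 for sterol genes. Those of day 4 minus untreated were 0.17 for Müller glia markers. Comparing day 4 minus day 2 gave 0.74 for proliferation. In cells with at least 2000 genes, values for day 2 minus untreated were -0.56 for homeostatic genes and 0.64 for ribosomal proteins. In the comparison day 4 minus untreated they were 1.11 for ribosomal proteins. With cells rescaled to the same sum, values for day 4 minus day 2 were 1.04 for proliferation and 0.46 for ribosomal proteins. With detected genes as a covariate, values for day 2 minus untreated were -0.0013 for Cd68, -0.49 for homeostatic genes, -0.15 for cytokines, -0.31 for complement, 0.29 for glycolysis, -0.12 for sterol genes, -0.55 for stress genes and 0.25 for ribosomal proteins. For day 4 minus untreated they were -0.60 for Fos, 0.20 for cytokines, 0.90 for interferon response, 0.57 for proliferation, -0.55 for complement, 1.20 for glycolysis, -0.063 for sterol genes, -0.98 for stress genes and 0.56 for ribosomal proteins. The values for day 4 minus day 2 were 0.52 for proliferation, -0.21 for antigen presentation, 0.0037 for sterol genes and 0.21 for ribosomal proteins. On the scale of log2 of the mean FPKM, values for day 2 minus untreated were 0.87 for cytokines, 1.06 for interferon response, 1.34 for proliferation, -0.056 for sterol genes, -0.0057 for stress genes and 0.23 for ribosomal proteins. Those of day 4 minus untreated were -0.16 for Nsdhl, -0.40 for Fos, 2.65 for proliferation, -0.70 for stress genes and 0.22 for ribosomal proteins. Comparing day 4 minus day 2 gave -0.51 for Pgk1, 1.19 for proliferation, -0.11 for antigen presentation, -0.076 for complement, 0.75 for glycolysis, 0.47 for sterol genes, -0.50 for stress genes and -0.16 for ribosomal proteins. Without the 3 cells under 1 M reads, values for day 4 minus day 2 were 0.36 for sterol genes. With expected cross-well reads removed, values for day 4 minus untreated were 0.68 for antigen presentation and 1.25 for ribosomal proteins. In the comparison day 4 minus day 2 they were 1.05 for proliferation, 0.51 for antigen presentation and 0.67 for ribosomal proteins. Relative to the median of all genes, values for day 2 minus untreated were 0.098 for disease-associated genes, -0.068 for complement, -0.052 for sterol genes and 0.21 for ribosomal proteins. For day 4 minus untreated they were -0.53 for antigen presentation, -0.089 for complement, 0.011 for sterol genes and 0.53 for ribosomal proteins. The values for day 4 minus day 2 were 0.64 for proliferation, -0.12 for antigen presentation, 0.0040 for sterol genes and 0.14 for ribosomal proteins. Leaving out each plate in turn, the range for day 2 minus untreated was -0.45 to 0.034 for homeostatic genes, 0.23 to 0.64 for disease-associated genes, 0.31 to 0.75 for glycolysis, -0.11 to 0.22 for sterol genes and 0.42 to 0.58 for ribosomal proteins. For day 4 minus untreated it was -0.50 to 0.023 for microglia markers, -1.24 to -0.17 for border macrophage markers and -0.69 to -0.027 for Müller glia markers. For day 4 minus day 2 it was 0.66 to 0.84 for proliferation, -0.090 to 0.20 for antigen presentation, 0.13 to 0.38 for sterol genes and 0.41 to 0.46 for ribosomal proteins.

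At an FPKM above 0, the shares of untreated cells with Gpr84, Tnf, Il1a, Gpr84 and Tnf, and Gpr84 and Il1a were 100%, 98.1%, 100%, 98.1% and 100%. Of cells of day 2 they were 100%, 100%, 100%, 100% and 100%. Of cells of day 4 they were 100%, 100%, 100%, 100% and 100%. At an FPKM of at least 5, the shares of untreated cells with Gpr84, Tnf, Il1a, Gpr84 and Tnf, and Gpr84 and Il1a were 42.6%, 37%, 74.1%, 22.2% and 42.6%. Of cells of day 2 they were 46.3%, 38.9%, 72.2%, 31.5% and 42.6%. Of cells of day 4 they were 75%, 72.2%, 88.9%, 63.9% and 69.4%. At an FPKM of at least 20, the shares of untreated cells with Gpr84, Tnf, Il1a, Gpr84 and Tnf, and Gpr84 and Il1a were 29.6%, 18.5%, 38.9%, 11.1% and 22.2%. Of cells of day 2 they were 38.9%, 29.6%, 55.6%, 24.1% and 33.3%. Of cells of day 4 they were 69.4%, 66.7%, 72.2%, 58.3% and 63.9%. Leaving out each plate in turn, the share at 1 FPKM was 97.2% to 100% for Il1a in untreated cells, 95.8% to 100% for Gpr84 at day 4 and 95.8% to 100% for Gpr84 with Il1a at day 4. In untreated cells with at least 2000 genes Il1a was at 100%.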

Other observations

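In this part the lists of protein complexes, the choice of Mki67 and the tests on other wells, with the comparison to all genes, on sequencing depth and on plate alone were chosen after the results were seen; the tests on the most abundant genes and on co-occurrence were set before their results were seen. Lists of the proteasome, the CCT chaperonin and ribosomal RNA processing were higher at day 4. The lists of protein complexes were run in the main setting only. How they change with detected genes as a covariate, on the log2 of the mean FPKM or without a plate was not tested. The 20S proteasome core had a median difference from untreated cells of 2.20 over 14 members (percentile 100 of random lists, by plate 1.86, 2.26 and 2.28), and 1.90 without the 2 members already named. The 19S regulator had a median of 2.05 over 17 members, with 15 higher in all 3 plates, and the CCT chaperonin, which folds actin and tubulin, 2.31 over 8 members, with 8 higher in all plates. Proteins of snoRNPs and ribosomal RNA processing had a median of 1.55 over 14 members, and the Ran cycle and nuclear transport 1.31 over 10. Without members already named, these were 1.48 over 13 and 1.11 over 7 (by plate 0.11, 1.66 and 1.46). At day 2 the 5 lists without members already named had percentiles of 93.4, 78.7, 43.5, 30.4 and 86.5, and the 20S core then had medians of 0.19, 0.47 and 1.49 by plate.

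Respiratory genes were higher at both time points. Complex I had a median of 0.78 over 36 members at day 2 (percentile 99.99) and 1.45 at day 4 (percentile 99.6), and complexes III and IV with the ATP synthase 0.91 and 1.87 over 35 members (percentile 100 at both), and 0.87 and 1.82 over 33 without the 2 members already named. The MCM helicase, which is loaded onto DNA before replication and whose 6 members belong to the proliferation list, has 2 members not yet named. At day 4 Mcm7 differed from untreated cells by 1.57 (0.46, 2.46 and 1.79 by plate) and Mcm4 by 0.10 (-0.41, 0.99 and -0.27). Mki67, a marker of cycling cells, reached 20 FPKM in 0 of 54 untreated cells, 2 of 54 cells of day 2 and 5 of 36 cells of day 4 (13.9%, 95% interval 4.67% to 29.5%), where 0 of 54 allows up to 6.60%. Lysosomal hydrolases, a list without named members, had medians of 0.19 and 0.36 (percentiles 5.21 and 7.15).

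In most cells that were not high in Gpr84, Tnf or Il1a, a low value of these genes was still present, and a candidate explanation is reads from other wells of the same plate. Genes with over 95% of their reads in 1 cell were found in 70.0% of the other wells of its column, 24.5% of its row and 17.7% of the rest of its plate, at 0.032%, 0.029% and 0.016% of the source reads. Expected reads were computed at these rates less the 0.0061% found in wells of other plates. For cells under 20 FPKM, the median of reads over those expected was 1.47 for Gpr84, 1.44 for Tnf and 1.53 for Il1a, and wells with more expected reads held 1.41, 1.46 and 1.31 times the reads of the others. Over 8354 measured genes with at least 30 such cells these 2 measures had medians of 2.38 and 1, and 62.7% of the genes lay at or under 3 for the first and 56.1% above 1 for the second, while Ccl4 had 1.13 and 0.778. Among the 8354 genes, Gpr84, Tnf and Il1a lay at percentiles 8.70, 7.47 and 11.7 of the first measure. On the second they lay at 76.4, 78.1 and 68.5. Their low values were thus nearer to the reads expected from other wells than those of most genes. Low expression in the cells themselves is not excluded by these values and stays open, so a share of cells at 1 FPKM may not count cells that express the gene.

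More genes were detected at day 4 than in untreated cells, by 1126.5, 1896 and 378.5 genes between the medians in plates 1, 2 and 3. With cells thinned to 2 M reads the difference was 808.5, 1658.5 and 311.5 genes, a mean of 926 ± 681 (SD of 3 plates), which argues against depth as the whole cause. With the 20 genes with most reads left out of each cell and the rest thinned to 1 M reads it was 962, 1575.5 and 128.5 genes, a mean of 889 ± 726. In plates 1 and 2 this argues against a few abundant genes as the whole cause. Plate 3 cannot tell, since the difference there fell from 378.5 to 128.5 genes. For both tests the spread of such medians between cells was not estimated. More RNA per cell and a better yield of cDNA in the rows of day 4 stay open, since no spike-in was analysed here and rows and time points coincide.

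The high values of Gpr84, Tnf and Il1a in the same cells may reflect cells that hold more of every transcript. Over the 3 time points 40 cells were high in Gpr84 and Tnf where 25.9 were expected, and 53 in Gpr84 and Il1a where 35.9 were expected. Within each plate of a time point 29.7 and 39.4 were expected, and within plate, time point and upper or lower part of the genes detected 34.6 and 46.4, which leaves 38.1% and 38.8% of the excess, with 1.94, 0.67 and 2.78 cells by plate for Tnf and 1.33, 3.11 and 2.17 for Il1a. Of the excess within plates alone, the split by genes detected leaves 52.4% and 48.8%. The bounds set beforehand were for strata that combine plate with genes detected, and 38.1% lies between them, so a link between the 3 genes and a general difference between cells cannot be told apart with these cells.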
